A study of Mus musculus with 5 samples.

How the data were processed

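RNA from mouse embryonic stem (ES) cells carrying a doxycycline-inducible Satb2 transgene (tetO-Satb2) was measured on 5 single-colour, biotin-labelled gene expression arrays. The table holds 35557 probe sets on every array, and no column was left unmapped. Arrays were assigned to a group and a replicate number from their titles. Uninduced cells gave 2 arrays (control 1 and 2) and doxycycline-induced cells 3 (DOX 1, 2 and 3). The labels do not say whether a replicate number stands for a clone, a culture or a day. All p-values therefore measure the spread between these 5 samples, which may be technical, and the number of arrays limits the precision.

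The deposited values are log2 signals that the authors made with RMA, per the submitters' processing notes, which name RMA and nothing more. RMA in its usual form corrects the background, quantile-normalizes the arrays and summarises each probe set by median polish. The software version, the genome build and the probe-set definition are not given in the sources used here. The log2 scale was read from the values, which ran from 1.18 to 13.3 with array medians between 5.61 and 5.68. Scanner files were not used here, so detection above background was not tested. Probe sets were named from GEO's platform annotation, and symbols were looked up through their Entrez identifiers in the RefSeq table of the GRCm38.p6 assembly, where 21698 matched and none changed. Of the probe sets, 21789 named 1 gene, 1621 named several and were not used, and 12147 were unnamed here. No probe set in that annotation named Satb2. A gene was read by the probe set with the highest mean over all 5 arrays, which gave 19938 genes. No coordinates are given, because the build behind the probe sets is not stated. Signals of near-identical gene copies are not separated here.

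Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, DOX minus control over all 5 arrays with group as the only term, and p-values were adjusted by Benjamini and Hochberg over the 19938 genes with a threshold of 0.05. All tests were two-sided. A fold change is a difference of mean log2 signals and its error is limma's moderated standard error (SE). An exact permutation test of 2 arrays against 3 cannot go below p = 0.1.

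Many values were exactly equal between arrays. In 72.4% of the genes at least 2 arrays of a group held the same value, and 2083 genes were identical on all 5 arrays. Median polish of few arrays can return such ties. They pull limma's prior variance to 8.54e-05 on 0.541 degrees of freedom, against 0.00751 on 3.19 degrees of freedom when the prior is estimated from the 5493 genes without a tie inside a group. This second prior, applied to every gene, was added after the data had been seen and is called the tie-free prior. In simulations of DOX against control with 67, 67 and 66 of 19938 genes changed by these sizes, added to the deposited residuals with their ties, limma recovered 58.2% of the 2^0.5-fold changes, 77.6% of the 2-fold and 87.9% of the 4-fold changes, and with the tie-free prior 73.1%, 97.0% and 100%. These residuals were centred within each group, so unchanged genes had no difference and a false call was not possible. The added changes carried no sampling error either, so these shares do not estimate recovery in real data. In simulated normal values without ties both priors coincide by construction, so their results are not a comparison. There limma recovered 43.3%, 86.6% and 97.0%, with 10 false calls.

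Before the data were examined, 28 gene lists with 395 genes were fixed, of which 361 genes were measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. The rule for named genes was also fixed beforehand. It took Satb1 and Nanog and, in each direction, the 10 largest changes among genes past the threshold whose groups did not overlap and whose higher group had a mean of at least 6. Where fewer passed, it filled up with genes at an unadjusted p under 0.01. From each list it took up to 4 members with the smallest p. Alternatives fixed at that stage were centring or quantile-normalizing the arrays again, mean-level filters of 5 and 7, the mean of a gene's probe sets, every probe set, an intensity trend and robust prior, array weights, the replicate number as a block, leaving out each array, and thresholds of 0.1 or 1.5-fold. Added after the data had been seen were the tie-free prior, with all arrays and with each left out, the genes without ties alone, and every probe set naming 1 gene. Shifting arrays against each other, as centring and quantile normalization do, also breaks exact ties. The table has no identifiers of the control type that the plan meant to leave out of the fit over every probe set, so that fit held all 35557.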

Results

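Gene expression was profiled in tetO-Satb2 mouse ES cells with and without doxycycline (DOX), which switches on a transgene for Satb2, a nuclear matrix-attachment protein that binds AT-rich DNA. The cells were kept with leukaemia inhibitory factor and serum, induced for 24 h and harvested 48 h after passaging. The labels describe growth on irradiated feeder fibroblasts, which were depleted by letting the suspension settle for 10 min and taking its upper 50%, while the design text speaks of leukaemia inhibitory factor only. The comparison asks which transcripts differ when Satb2 is overexpressed in undifferentiated cells. It rests on 2 control and 3 DOX arrays, whose median log2 signals lay between 5.61 and 5.68. Pearson's r across genes between pairs of arrays was 0.995 to 0.998. DOX 1 stood apart on the first principal component, which held 47.7% of the variance.

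No gene passed an adjusted p of 0.05 in limma over 19938 genes. An unadjusted p under 0.05 was reached by 281 genes, 129 higher and 152 lower with DOX, against 997 expected by chance, and the smallest adjusted p was 0.259. Changes were small. Only Cspp1 differed by at least 2-fold, and 17 genes differed by 0.5 or more on the log2 scale. The numbers of genes under a p-value threshold depend on the tied values described with the processing. With the tie-free prior, chosen after the data had been seen, 190 genes had an unadjusted p under 0.05 and 1 gene, Cspp1, passed the threshold.

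Cspp1, which encodes a centrosome and spindle pole protein, had the largest difference of any named gene. Its brightest probe set gave 7.86 ± 0.02 (SD, n = 2) in control cells and 9.20 ± 0.07 (SD, n = 3) with DOX, a difference of 1.34 ± 0.05 (SE) or 2.53-fold. The adjusted p was 0.292 in limma and 0.018 with limma and the tie-free prior. The gene has 14 probe sets. Of these, 13 were higher on all DOX arrays than on both control arrays, by 1.34 to 2.03 on the log2 scale, and the other held one value on all 5 arrays. With the tie-free prior over every probe set naming 1 gene, those 13 probe sets passed the threshold and no other did. Over every probe set in the table, with the same prior, 0 of them passed in limma (adjusted p = 0.177 for the brightest). Without control 1, control 2, DOX 1, DOX 2 or DOX 3 the tie-free adjusted limma p of Cspp1 was 0.661, 0.585, 0.0591, 0.119 and 0.0781, with log2 differences between 1.31 and 1.38. With limma's own prior Cspp1 passed after all 5 arrays were centred again on their medians. It also passed among the genes without ties. Against a lone control array it passed with limma's own prior, at 1.32 without control 1 and 1.35 without control 2.

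No named probe set read Satb2, so induction of the transgene was not checked by name. One unnamed probe set, 10354777, had the largest difference of the whole table, from 5.37 ± 0.11 (SD, n = 2) to 9.11 ± 0.05 (SD, n = 3), a 13.4-fold higher signal with DOX. Its adjusted p over all 35557 probe sets was 0.0671 in limma and 0.0108 with limma and the tie-free prior. The related gene Satb1 was at 6.08 ± 0.03 (SD, n = 2) and 5.98 ± 0.10 (SD, n = 3), a difference of -0.10 ± 0.07 (SE) with an adjusted limma p of 0.877.

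Among genes with an unadjusted limma p under 0.01, no overlap between the groups and a mean of at least 6 in the higher group, the largest differences upwards after Cspp1 were in Dpp4, a cell-surface dipeptidyl peptidase (0.65 ± 0.07, SE), Elobl (0.58 ± 0.08), 2210409E12Rik (0.58 ± 0.11), Otx2, a homeobox factor of the epiblast (0.55 ± 0.05), and Lrp2, the endocytic receptor megalin (0.51 ± 0.04). The imprinted gene Peg10 (0.30 ± 0.05), the adhesion receptor gene Adgrl2 (0.28 ± 0.03), the ubiquitin ligase gene Ubr3 (0.22 ± 0.02) and the membrane peptidase gene Mme (0.20 ± 0.04) followed. Under the same limits, which leave out larger falls such as that of Egln3 given further on, the largest differences downwards were in Zic2, a zinc-finger factor of the epiblast and neural plate (-0.43 ± 0.06), the fatty acid desaturase gene Scd2 (-0.34 ± 0.05), the growth factor gene Pdgfc (-0.30 ± 0.06), the pseudogene Anp32-ps (-0.26 ± 0.05) and Enox1 (-0.25 ± 0.05). A430033K04Rik (-0.20 ± 0.03), the vesicle fusion gene Vamp7 (-0.19 ± 0.03), Zfp759 (-0.17 ± 0.01), the glypican gene Gpc4 (-0.16 ± 0.03) and the calpain subunit gene Capns1 (-0.15 ± 0.02) completed the 20. These errors depend on the prior, and with the tie-free prior the SE was 0.06 for each of Zfp759, Gpc4 and Capns1. The unadjusted limma p with that prior was above 0.01 for these genes, A430033K04Rik, Vamp7 and Mme, at 0.016 to 0.039. With the deposited values of all 5 arrays and limma's own prior, none of these 20 passed the threshold over all genes. Cspp1 passed after the arrays were centred again on their medians, and with the tie-free prior. Zfp759 passed against a lone control array, at -0.15 without control 1 and -0.18 without control 2. With the tie-free prior Zfp759 did not pass there. The arrays of these 20 genes did not overlap between groups, a property that 925 of the 19938 genes (4.64%) had. Chance gives it to 20% of genes without ties, a share that does not apply here, as 72.4% of the genes held ties. Other splits of the 5 arrays into 2 and 3 set 643 to 2283 genes apart. The signal of the pseudogene Anp32-ps is not separated from that of near-identical copies.

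**Figure D1:**
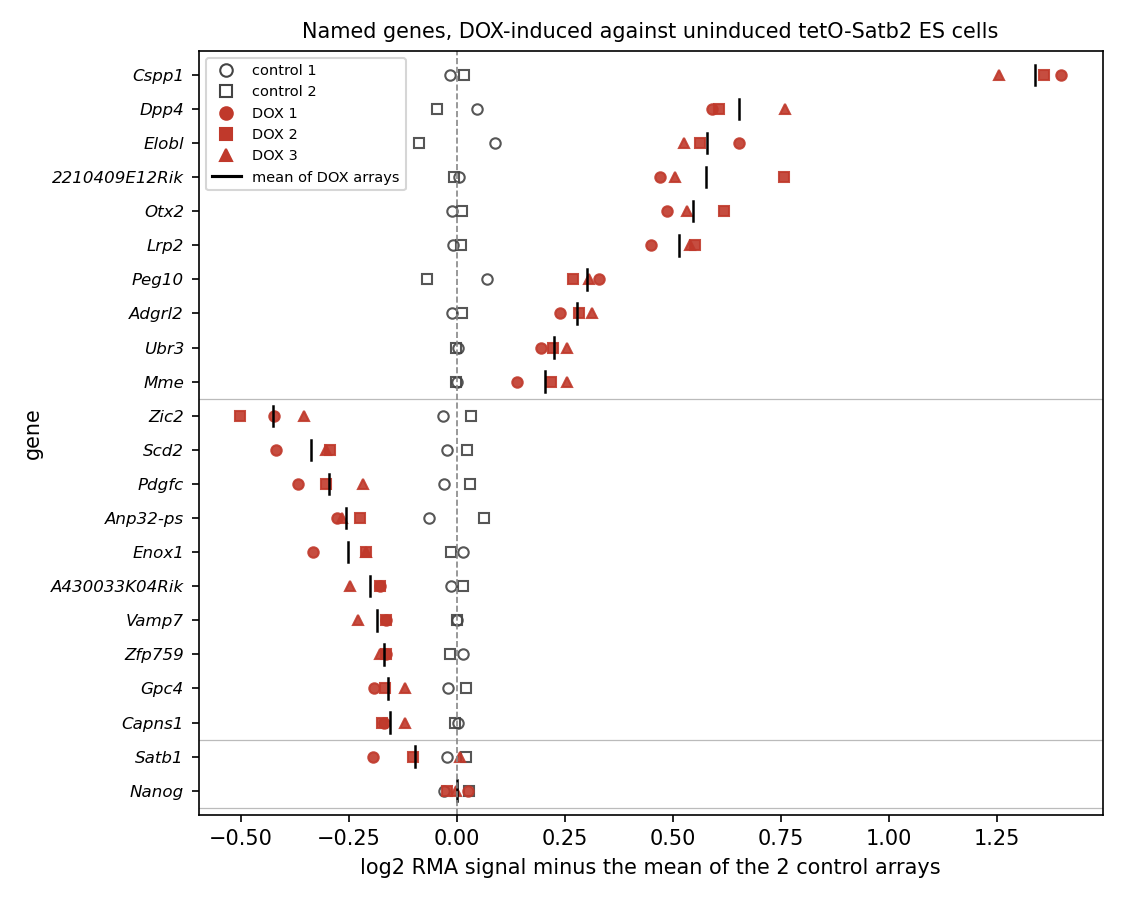
The horizontal axis gives the log2 RMA signal of each array minus the mean of the 2 control arrays, for Satb1, Nanog and 20 genes, the 10 largest differences in each direction among genes with an unadjusted limma p under 0.01, no overlap between groups and a mean of at least 6 in the higher group. Open symbols are control arrays, filled symbols DOX arrays, and black bars the mean of the 3 DOX arrays; Cspp1 stands at 1.34 and the next of these genes, Dpp4, at 0.65.

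Genes of glycolysis and of the hypoxia response fell as a group, with an adjusted camera p of 7.58e-10. The call is lost with an estimated correlation (adjusted p = 0.863 with an estimated correlation, unadjusted p = 0.0924), and fry gave p = 0.0506 for a common direction. Of the 18 measured members 16 were lower with DOX, 15 of them on every DOX array, and the median difference was -0.22 on the log2 scale. The mean of the list was 8.24 ± 0.13 (SD, n = 2) in control cells and 7.96 ± 0.05 (SD, n = 3) with DOX, a 1.22-fold lower level. The largest differences of the list were in Egln3, the oxygen-sensing prolyl hydroxylase induced by hypoxia (-0.90 ± 0.20, SE), the mitophagy gene Bnip3 (-0.70 ± 0.14), and Adm, which encodes adrenomedullin (-0.54 ± 0.16). The phosphofructokinase genes Pfkp (-0.42 ± 0.12) and Pfkl (-0.41 ± 0.14) differed by less, as did Ldha, which makes lactate dehydrogenase (-0.28 ± 0.07), and Pgk1, which makes phosphoglycerate kinase (-0.25 ± 0.06). Vegfa (-0.05 ± 0.05), Pdk1 (0.04 ± 0.04) and Car9 (0.04 ± 0.10) did not differ by more than their error. Adm, Pfkp, Pfkl, Vegfa, Pdk1 and Car9 lie outside the rule for named genes and were chosen after their values were seen. No member passed over all genes and 0 passed adjusted over the list alone in limma, where 7 had an unadjusted p under 0.05; with the tie-free prior 7 fell, adjusted over the list alone. The 2 control arrays themselves differed, at 8.15 and 8.33, and without control 2 the median difference was -0.15 with an adjusted camera p of 0.0107. Without DOX 1, the array that stood apart, the median difference was -0.23 with an adjusted camera p of 8.4e-06.

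**Figure D2:**
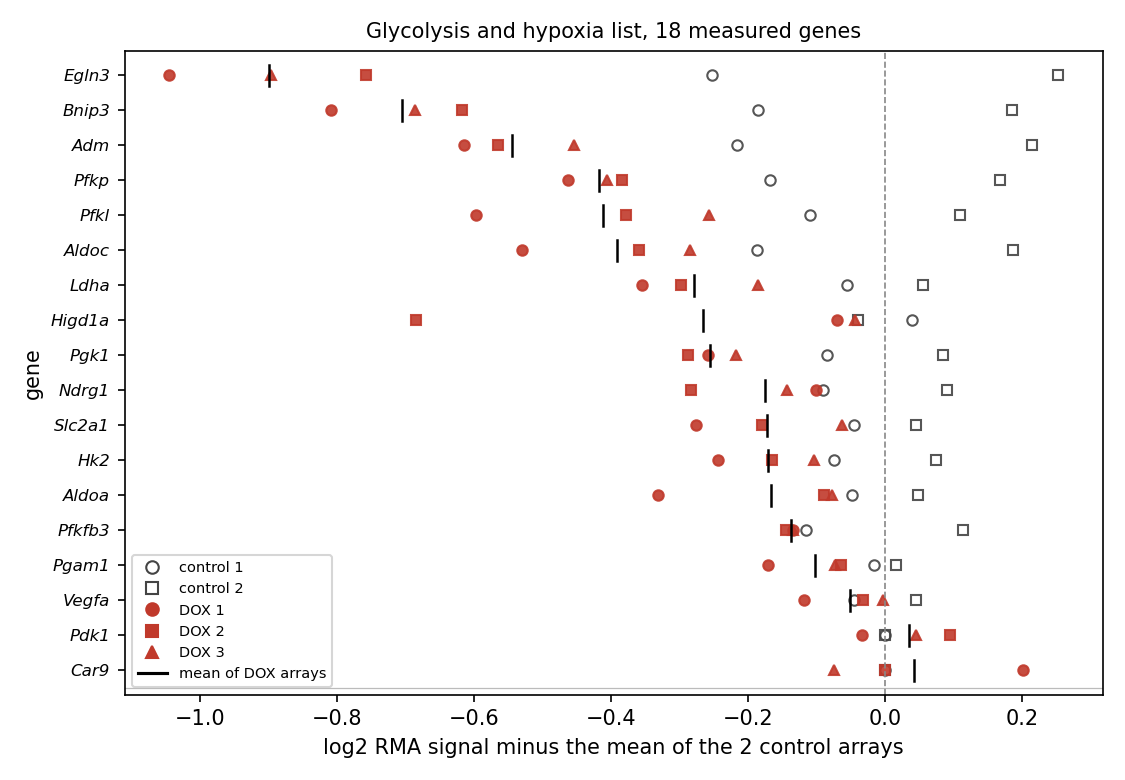
The horizontal axis gives the log2 RMA signal of each array minus the mean of the 2 control arrays for the 18 measured genes of the glycolysis and hypoxia list, ordered by difference. Open symbols are control arrays, filled symbols DOX arrays and black bars the DOX means; 15 genes lie lower on all DOX arrays than on both control arrays, while control 2 is above control 1 for most of them.

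Core pluripotency genes showed no difference that passed a test. Nanog measured 9.93 ± 0.04 (SD, n = 2) and 9.93 ± 0.02 (SD, n = 3), a difference of 0.00079 ± 0.026 (SE). The differences of Pou5f1 (-0.0080 ± 0.068) and Sox2 (0.051 ± 0.033) did not pass either. They were chosen after their values were seen. Of the 13 measured core genes 8 were higher and 5 lower, with a median of 0.01, and none passed adjusted over the list alone; the smallest p belonged to the co-receptor gene Tdgf1 (-0.12 ± 0.02), followed by Gdf3 (-0.09 ± 0.04), Sall4 (0.03 ± 0.02) and Dppa2 (0.04 ± 0.02). In limma Sall4 passed over all genes only with control 1 left out, at a difference of 0.05 from a lone control array. With the tie-free prior Sall4 did not pass there. The adjusted camera p of the list was 0.796.

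Genes of naive pluripotency differed in both directions. The orphan receptor gene Nr0b1 (-0.27 ± 0.06, SE) and Klf4 (-0.26 ± 0.07) were lower on all DOX arrays, and Klf2 (0.23 ± 0.06) and Dppa3 (0.25 ± 0.11) were higher on all of them. None of the 15 members passed over all genes or adjusted over the list alone. Camera found no common direction (adjusted p = 0.769), whereas fry's test for changes in either direction gave an adjusted p of 0.0030 over the 28 lists. Among the 12 formative and primed epiblast genes, Otx2 rose and Zic2 fell, with limma p-values adjusted over the list alone of 0.0073 and 0.016. No member passed over all genes. Dnmt3a, a de novo DNA methyltransferase gene, differed by 0.23 ± 0.06 and Etv5 by -0.04 ± 0.03. The list had an adjusted camera p of 0.928 and an adjusted fry p in either direction of 0.0069.

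The neuroectoderm list also fell by a small amount. Of 13 members 11 were lower and 2 higher, with a median of -0.04, and the adjusted camera p was 0.0089. The call is lost with an estimated correlation (adjusted p = 0.863 with an estimated correlation), and without control 1, control 2, DOX 2 or DOX 3 (adjusted p of 0.237, 0.106, 0.0526 and 0.116). The RNA-binding protein gene Msi1 (-0.17 ± 0.04, SE), Sox11 (-0.21 ± 0.09), Pax6 (-0.08 ± 0.04) and Neurog2 (-0.04 ± 0.03) had the smallest p. No member passed over all genes or adjusted over the list alone. In limma Msi1 passed over all genes only with control 2 left out, at a difference of -0.22 from a lone control array. With the tie-free prior Msi1 did not pass there.

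Other lineage lists were not called. Adjusted camera p-values were 0.928 for primitive streak and mesoderm (median 0, with Fgf8 at -0.18 ± 0.09, SE), 0.527 for extraembryonic endoderm (median -0.01, with Lama1 at -0.07 ± 0.03) and 0.790 for trophoblast (median 0.01, with Elf5 at 0.05 ± 0.04). They were 0.918 for the 2-cell-like state, where 4 genes were measured (Zfp352 at -0.25 ± 0.23), 0.224 for germ line genes (Kit at 0.15 ± 0.03) and 0.908 for Hox genes (Hoxd4 at -0.07 ± 0.04). Mean signals of the primitive streak, trophoblast, 2-cell-like and Hox lists lay between 4.18 and 5.57, below the array medians, and detection was not tested. The bone and cortex genes linked to Satb2 elsewhere had a median of 0 over 7 measured members, with Alpl at 0.10 ± 0.07. Alpl read 6.52 on control 1, 6.71 on control 2 and 6.71 to 6.72 on the DOX arrays. The adjusted camera p of this list was 0.928. Imprinted genes, with Peg10 among them, stood at 0.859, epithelial adhesion at 0.615 (Jup at 0.17 ± 0.08) and mesenchymal transition at 0.790 (Twist1 at 0.07 ± 0.08). Without DOX 1 the epithelial adhesion and germ line lists were called higher (adjusted camera p of 0.0053 and 0.0406), and the germ line list also with array weights (0.0351). With an estimated correlation their adjusted p = 0.980 and 0.909, and over all settings they ranged from 0.0053 to 0.996 and from 0.0351 to 0.948. With all 5 arrays no member of these lists passed over all genes or adjusted over its list alone. In limma, fits with 1 control array left out called Alpl, Kdr, Sox17, Hoxb1, Tex101, Ibsp and Snai1 over all genes. Such a call rests on a lone control array and on DOX values that are equal or nearly so. With the tie-free prior none of these genes was called in those fits. For Kdr, Sox17, Hoxb1, Tex101 and Ibsp the control array left out held the same value as every DOX array.

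Markers of feeder fibroblasts were examined because feeders shared the culture. Of 23 measured markers 11 were higher, 6 lower and 6 equal, with a median of 0. The matricellular gene Ccn1 (0.30 ± 0.07, SE), Thbs1 (0.17 ± 0.04), the intermediate filament gene Vim (0.15 ± 0.05) and Tagln (0.14 ± 0.08) were higher on all DOX arrays. The collagen genes Col1a1 (0.01 ± 0.01), Col1a2 (0.06 ± 0.04) and Col3a1 (-0.01 ± 0.01), chosen after their values were seen, stayed near 0. No member passed. The list's adjusted camera p was 0.11. It was called higher after quantile normalization (0.0471), at a mean level of at least 5 (0.0327) or 7 (0.0092), among genes without ties (0.0183) and with the tie-free prior (0.0407). With an estimated correlation its adjusted p = 0.863, and over all settings it ranged from 0.0092 to 0.948. The sex-linked genes used as a clone check had an adjusted camera p of 0.567. Xist was at 4.53 in both groups and the Y-linked Eif2s3y at 7.72 and 7.68.

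Signalling and stress lists were also below the threshold. The p53 list had 8 members higher and 4 lower, with Mdm2, the p53 ubiquitin ligase gene, at 0.11 ± 0.02 (SE) and Ei24 at 0.24 ± 0.06, and an adjusted camera p of 0.11. It was called higher at a mean level of at least 5 (0.0254) or 7 (3.0e-04), with array weights (0.0351) and without DOX 1 (0.0176). With an estimated correlation its adjusted p = 0.909, the highest of all settings. The integrated stress response list had 14 of 18 members lower, with Nupr1 at -0.25 ± 0.12, Ddit4 at -0.37 ± 0.18, Atf4 at -0.12 ± 0.08 and Chac1 at -0.17 ± 0.12. Its adjusted camera p was 0.0563. It was called lower after centring (0.032) or quantile normalization (0.0156), at a mean level of at least 5 (0.0339), over every probe set (0.0461), without control 1 (0.0159) or DOX 2 (0.0298) and with the tie-free prior (0.0048). With an estimated correlation its adjusted p = 0.909, and over all settings it ranged from 2.4e-05 to 0.949, the latter without control 2. In the immediate early and ERK feedback list the phosphatase genes Dusp4 (0.25 ± 0.06) and Dusp6 (0.24 ± 0.10) were higher on all DOX arrays, with an adjusted camera p of 0.918. The adjusted camera p was 0.527 for TGF-beta and BMP targets (Skil at -0.28 ± 0.07, Lefty1 at -0.27 ± 0.12), 0.59 for Wnt targets (Ccnd1 at -0.29 ± 0.13), 0.863 for LIF and STAT3 (Lifr at 0.05 ± 0.03) and 0.859 for the interferon response (Ddx58 at -0.04 ± 0.01). It was 0.615 for oxidative phosphorylation (Cox7a2 at -0.08 ± 0.08), a list with 13 of 17 members lower that turned to higher and was called without DOX 1 (0.0024), with a range up to 0.980 over all settings, the latter with an estimated correlation. It was 0.992 for the cell cycle (Ccne1 at 0.07 ± 0.02), 0.908 for ribosome biogenesis (Nop58 at -0.05 ± 0.03) and 0.918 for chromatin regulators (Dnmt3l at -0.31 ± 0.11). With all 5 arrays no member of these lists passed over all genes or adjusted over its list alone. Over all genes Znrf3, a Wnt target, passed in limma only without control 1 (difference 0.11) and Id4, a BMP target, only without control 2 (0.20). Both calls rest on a lone control array and were lost with the tie-free prior. For each gene the control array left out held the same value as DOX 1. Camera's direction was opposite in sign to the list's median for the formative, epithelial adhesion, imprinted, cell cycle and interferon lists, and to the difference of the list's mean for the core pluripotency, primitive streak, cell cycle, Wnt and immediate early lists.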

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

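The unnamed probe set 10354777 stands out because it carries a strong signal in a part of the table that no gene comparison used. Its signal was 3.74 higher with DOX on the log2 scale, at 5.45 and 5.29 on the control arrays and at 9.08, 9.17 and 9.09 on the DOX arrays. Its limma p was adjusted over all 35557 probe sets with the tie-free prior, chosen after the data had been seen (0.0108). It was the only unnamed probe set past that threshold, and no gene is assigned to it here. No group held the 4 or more arrays that a test for single outlying arrays needs.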

How the results depend on the processing

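The tests with the tie-free prior, on genes without ties and on every probe set naming 1 gene were chosen after the results had been seen. The count of genes past the threshold was 0 and rose to 1, Cspp1, when arrays were centred again on their medians, with the tie-free variance prior, and among the genes without ties. It was 13 over every probe set naming 1 gene with the tie-free prior, all of Cspp1, and 1 over every probe set in the table with that prior, the unnamed 10354777. Leaving out 1 array gave 0 to 1333 genes, namely 909 without control 1 and 1333 without control 2, where the lone control array is assumed to vary like the DOX arrays. Of these calls 84.5% and 81.0% were genes with one identical value on all DOX arrays, against 20.3% of all genes, and with the tie-free prior both counts were 0. The number of called lists was 2. It became 3 after centring, at a mean level of at least 7, over every probe set in the table, among genes without ties, and over every probe set naming 1 gene with the tie-free prior. It became 4 after quantile normalization, with array weights and with the tie-free prior, 5 at a mean level of at least 5 and 0 with an estimated inter-gene correlation. It ran from 1 to 6 when 1 array was left out, and from 1 to 3 under the tie-free prior. For the glycolysis and hypoxia list the adjusted p ranged from 2.8e-08 to 0.0107 when 1 array was left out and ended at 0.863 with the estimated correlation. The neuroectoderm list lost its call with the replicate block (0.332), the estimated correlation (0.863), and every probe set with the tie-free prior (0.0935). It ranged from 0.0053 to 0.237 when 1 array was left out, and with the tie-free prior it was 0.171, 0.113, 0.0642 and 0.165 without control 1, control 2, DOX 2 and DOX 3. The oxidative phosphorylation list turned from lower to higher and was called without DOX 1 (adjusted p = 0.0024, or 0.0237 with the tie-free prior), against 0.949 without control 2. Snai1 was at -0.11 without control 1 and at 0.086 without control 2. The causes of these list changes were not tested. The neuroectoderm list had too few members for a value at a mean level of at least 7 and among genes without ties, and no named probe set gave a value for Satb2. The signal over background of single arrays was not used here.

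The shared replicate numbers 1 and 2 give 2 pairs, and the labels do not say that a number marks anything shared, so the block is not a paired design. The differences of number 1 minus number 2 in control and DOX cells correlated across genes with r = 0.13. With the replicate block 0 genes passed (smallest adjusted p = 0.753), and the glycolysis and hypoxia list was called (adjusted p = 4.8e-10), as was the integrated stress response list (0.0243). Number 3 occurs only with DOX, so DOX 3 adds nothing to the differences estimated with the block. The median of the glycolysis and hypoxia list was -0.250 both with the block and without DOX 3. These are therefore not separate checks of its size.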

Other observations

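The test of doxycycline stress, the splits of the arrays and the count of Cspp1 probe sets were chosen after the result had been seen. Genes that hypoxia-inducible factors are known to activate, and that were not in the glycolysis and hypoxia list, were listed afterwards but before their values were looked at. Of 13 measured, 12 were lower with DOX and 8 of them on every DOX array, with a median of -0.18 on the log2 scale. The oxidoreductase gene Ero1a differed by -0.33 ± 0.14 (SE), the prolyl hydroxylase genes P4ha1 by -0.30 ± 0.18 and P4ha2 by -0.16 ± 0.05, Ankrd37 by -0.28 ± 0.12, and the collagen lysyl hydroxylase gene Plod2 by -0.21 ± 0.07. The glucose transporter gene Slc2a3 (-0.17 ± 0.04), the histone demethylase gene Kdm3a (-0.15 ± 0.04) and the oxygen sensor gene Egln1 (-0.18 ± 0.05) were also lower on all DOX arrays, and Hilpda held one value on all arrays. None passed adjusted over the list alone in limma. Camera gave p = 6.8e-09, and 0.0582 with an estimated correlation.

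Of the 222 genes read by 3 or more probe sets, 5 had most of their probe sets apart between the groups. Besides Cspp1, Adgrl2 had 6 of 8 probe sets higher on all DOX arrays, with a median difference of 0.27. The remaining 3 genes had all 3 probe sets lower, namely Pgk1 (-0.26), the macrophage migration inhibitory factor gene Mif (-0.16) and Pgam1 (-0.10). Pgk1 and Pgam1 are in the glycolysis and hypoxia list. Their median difference equalled an end of the range over their probe sets (-0.2573 and -0.1027). Some of their probe sets thus gave equal differences and may not be separate readings.

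The lower glycolysis and hypoxia genes were weighed against 3 explanations. A shift of the normalized values that depends on signal level is argued against, because 0 of 10000 random lists matched on mean level had a median as low as -0.22 (lowest -0.07; percentile 0). Mitochondrial stress from doxycycline should raise the integrated stress response. With 1 array left out, the mean of that list differed by -0.117 (control 1), -0.045 (control 2 or DOX 1), -0.102 (DOX 2) and -0.096 (DOX 3). Over all 5 arrays it differed by -0.0811 ± 0.054 (SE over 5 arrays). Its 95% interval over arrays, -0.253 to 0.0906, takes in 0, so this explanation stays open. Lower activity of hypoxia-inducible transcription in the DOX cultures may account for the pattern. The 13 hypoxia genes outside the list had a median at percentile 0 of their own matched random lists. Those lists draw genes singly and do not allow for genes that move together, so the percentile cannot decide this. Camera with an estimated correlation gave p = 0.0582 for the 13 genes. Whether Satb2, doxycycline or a difference in culture density or oxygen lies behind the lower genes was not tested. Only 1 of the 10 splits of the 5 arrays, the real one, gave a difference of the list mean of 0.281, the highest other being 0.234, and 10 splits are too few for a share under 0.05.

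The higher Cspp1 signal is not the fault of a single probe set, as 13 of 14 were higher on all DOX arrays. Nor did its chromosomal neighbourhood move as a whole. The 20 nearest measured genes had a median difference of 0 (SD 0.07, range -0.19 to 0.12), and 0 of them were higher on all DOX arrays. All 5 arrays come from tetO-Satb2 cells, so a response to Satb2 and one to doxycycline itself cannot be told apart. These, and an effect of the transgene's own insertion on Cspp1, were not tested and may each account for the higher signal. The insertion site is not known here.

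Of the 10 splits of the arrays, 2 others set more genes apart than the real one, which gave 925 genes without overlap. Control 1 and DOX 1 against the other 3 arrays gave 2283, and DOX 2 and DOX 3 against the other 3 gave 1981. These counts point to a structure among the arrays besides the groups, and its source was not tested. On the first principal component DOX 1 was at 14.8 and the other arrays between -7.09 and -0.49.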
